A study of Mus musculus with 20 samples.

How the data were processed

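Single-end sequencing of poly(A)-selected RNA was carried out on the hippocampus and cortex of bulbectomised NMRI mice, with a directional library kit and RNA of an integrity number of at least 8, per the labels' protocols. From day 14 after surgery the animals had received intranasal human recombinant HSP70 (4 µg) or YB-1 (6.4 µg) for 21 days. The 20 libraries form 4 groups of 5, by tissue and treatment, as the labels give them. The labels describe the libraries of a group as separate samples but do not name the animal behind each.

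The deposited values are whole-number read counts per Ensembl gene, 1 file per library, with 55487 gene entries and 12 summary entries that name no gene. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with the GRCm39 assembly; their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart with certainty, and genes with near-identical copies, such as Hspa1a and Hspa1b, are uncertain. The summary entries were left out of library sizes and tests; reads outside any gene made up 2.45% to 4.58% and ambiguous reads 4.12% to 4.58% of a library. Gene symbols were matched by Ensembl identifier to GENCODE M21, an annotation of the earlier assembly, which was used for names, chromosome membership and transcript lengths only; 99.4% of identifiers, holding 99.98% of assigned reads, had a symbol. No coordinates are given, because the builds differ.

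Assigned reads per library ranged from 6414215 to 15148078. No pair of libraries within a group was a duplicate: the chi-square of their counts per degree of freedom was at least 10.8. Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, a robust quasi-likelihood fit and two-sided F-tests, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Treatments were compared within each tissue alone, and the interaction and the tissues in a model of all 4 groups. CPM values are TMM-scaled, and log2 CPM use a prior count of 2. P-values of single genes and of list scores measure the spread between these libraries. Those of the list test with a preset correlation, described below, rest mainly on the spread between genes. The interaction and tissue models take same-numbered libraries of the 2 tissues as independent, except where the animal is a block.

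Gene lists of cell types, brain regions, pathways and complexes were written before the data were examined, 49 in all, of which 47 with at least 5 tested members entered the list tests. Of their 896 symbols, 876 matched the annotation. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists, and beside it with an estimated correlation and with fry. A list's score is the mean log2 CPM of its members with a mean of at least 1 CPM, and scores were compared by two-sided exact permutation tests over 252 assignments, whose smallest possible p is 0.0079. Correlations over the 10 animals were tested with 100000 resamples, 2 relations in the family.

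The genes named follow a rule fixed beforehand: the 4 chaperone genes; in each treatment comparison the 5 genes with a symbol and the smallest p in each direction, since fewer than 5 passed; the 3 members with the smallest p of each list that passed and of 8 lists of prior interest; and between tissues the 5 with the smallest p in each direction and 2 members of each regional marker list. Some genes that the rule takes are not reported here.

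Whether equal replicate numbers mark shared animals was checked by correlating the deviations of libraries from their group means over 13978 genes. Between hippocampus and cortex of a treatment all 10 same-numbered pairs exceeded 0.1 (HSP70 0.211 to 0.66, YB-1 0.221 to 0.418), so the numbers pair the tissues. The hippocampal library correlated best with its own number in 5 of 5 HSP70 and 4 of 5 YB-1 pairs; YB-1 replicate 1 correlated more with cortical replicate 5 (0.363) than with cortical replicate 1 (0.221). Between treatments they did not (-0.304 to 0.525 in the hippocampus, -0.155 to 0.19 in the cortex).

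The gene tests were tried on counts simulated from the libraries' means and depths, with 67, 67 and 66 genes changed 1.5, 2 and 4-fold. The share of changed genes recovered at these sizes was 11.9%, 56.7% and 86.4% in the hippocampal design, 11.9%, 64.2% and 89.4% in the cortical design, 2.99%, 22.4% and 75.8% for the interaction and 47.8%, 74.6% and 97% between tissues. Unchanged genes made up 6 of 109 calls in the hippocampal design, 5 of 115 in the cortical design, 2 of 69 for the interaction and 13 of 159 between tissues. In simulated lists raised 1.5-fold, 5 of 5 were recovered in each comparison. Of 35 unchanged lists, 1 was called in the hippocampal design, 0 in the cortical design, 1 for the interaction and 0 between tissues. The simulated genes are independent, unlike real ones.

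Alternatives covered DESeq2-type (RLE) and upper-quartile scaling, no low-count filter and a stricter one (CPM of at least 1 in 5 libraries), a non-robust fit, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable (sva 3.50.0), all 20 libraries in 1 fit, blocks for replicate number or animal, and leaving out each library. Log2 Bc1 share as a covariate, both tissues averaged with the animal as a random effect, and leaving out 2 libraries that stand apart were added after the data were seen. Figures were drawn with matplotlib in Python.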

Results

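RNA was sequenced from the hippocampus and the cortex of bulbectomised NMRI mice, an outbred stock in which surgical removal of the olfactory bulbs serves as a model of sporadic Alzheimer's disease. The mice had received a recombinant human chaperone through the nose, either HSP70, the stress-inducible heat shock protein, or YB-1, a DNA- and RNA-binding cold shock protein. Each treatment in each tissue was represented by 5 libraries, 20 in all. Every comparison of treatments is YB-1 against HSP70 in animals that had all been operated. Animals without surgery or given vehicle were not analysed here, so a higher value with YB-1 can equally be read as a lower value with HSP70.

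The hippocampal libraries held 7756835 to 13053910 reads assigned to genes with HSP70 and 7236195 to 10166968 with YB-1. In the cortex the treatments did not overlap in depth, with 12283392 to 15148078 reads in the HSP70 group and 6414215 to 10763465 in the YB-1 group. Between 16889 and 20712 genes had at least 1 read in a library. Bc1, a short noncoding RNA of neurons, took 3.92% to 20.8% of the assigned reads of a library with ranges that overlapped between treatments in both tissues. Immunoglobulin genes also varied widely between animals, from 539.5 to 8568 CPM (counts scaled to a common library size). No library held a read of Xist, and the Y-linked gene Ddx3y had reads in all 20.

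**Figure D1:**
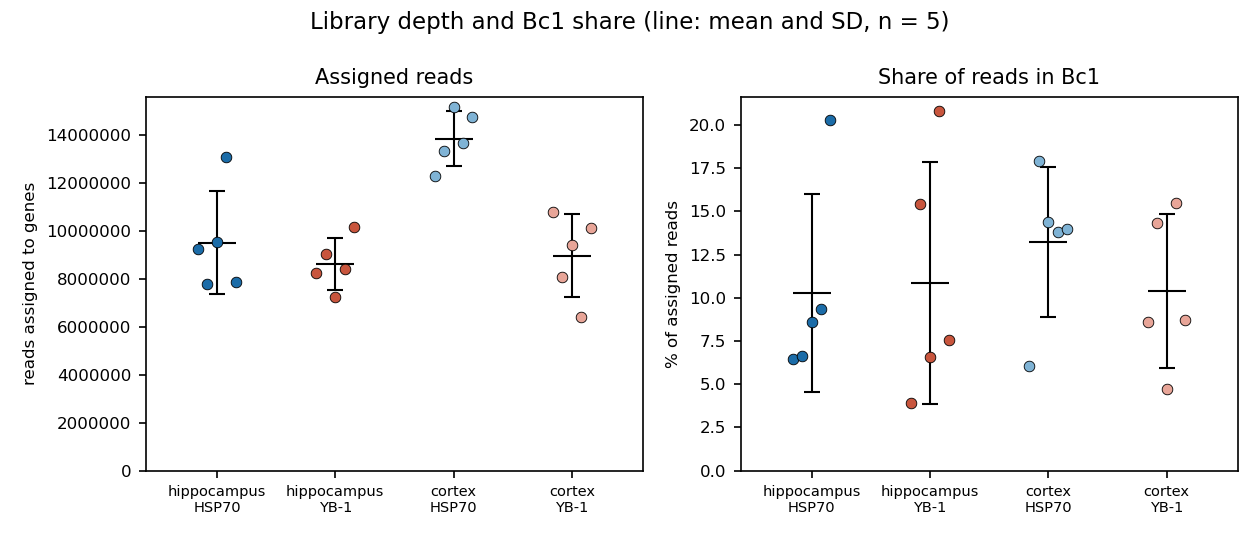
Reads assigned to genes (left) and the percentage of them in Bc1 (right) for each library, with 1 point per library and the mean and SD of each group of 5. The cortex YB-1 libraries, at 6414215 to 10763465 reads, all lie below the cortex HSP70 libraries, at 12283392 to 15148078.

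The mouse's own genes for the delivered proteins were examined first, since the treatments differ in these proteins. None of the 4 passed the test between treatments in either tissue, which does not exclude a difference. Hspa1a (ENSMUSG00000091971), an inducible HSP70 gene, was at 4.14 ± 2.21 CPM with HSP70 and 2.63 ± 0.67 CPM with YB-1 in the hippocampus (mean ± SD, n = 5). Its log2 fold change was -0.63 ± 0.40 (SE). In the cortex its values were 2.75 ± 0.57 and 2.32 ± 0.87 CPM. Hspa1b (ENSMUSG00000090877), a near-identical copy of Hspa1a whose reads cannot be told apart with certainty, was at 10.2 ± 3.002 and 11.02 ± 1.32 CPM in the hippocampus. In the cortex it was at 14.1 ± 3.64 and 10.9 ± 1.80 CPM. Hspa8 (ENSMUSG00000015656), the constitutive member of the family, stood near 1000 CPM everywhere, with log2 fold changes of -0.03 ± 0.11 in the hippocampus and 0.01 ± 0.13 in the cortex. Ybx1 (ENSMUSG00000028639), which encodes mouse YB-1, was at 146 ± 23.7 CPM with HSP70 and 128 ± 27.6 CPM with YB-1 in the hippocampus, and at 113 ± 15.3 and 132 ± 28.3 CPM in the cortex. The adjusted p of edgeR's quasi-likelihood test was 1 for all 4 genes in the hippocampus and at least 0.858 in the cortex. The signs for Hspa8 in both tissues and for Hspa1b in the hippocampus depended on the processing.

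**Figure D2:**
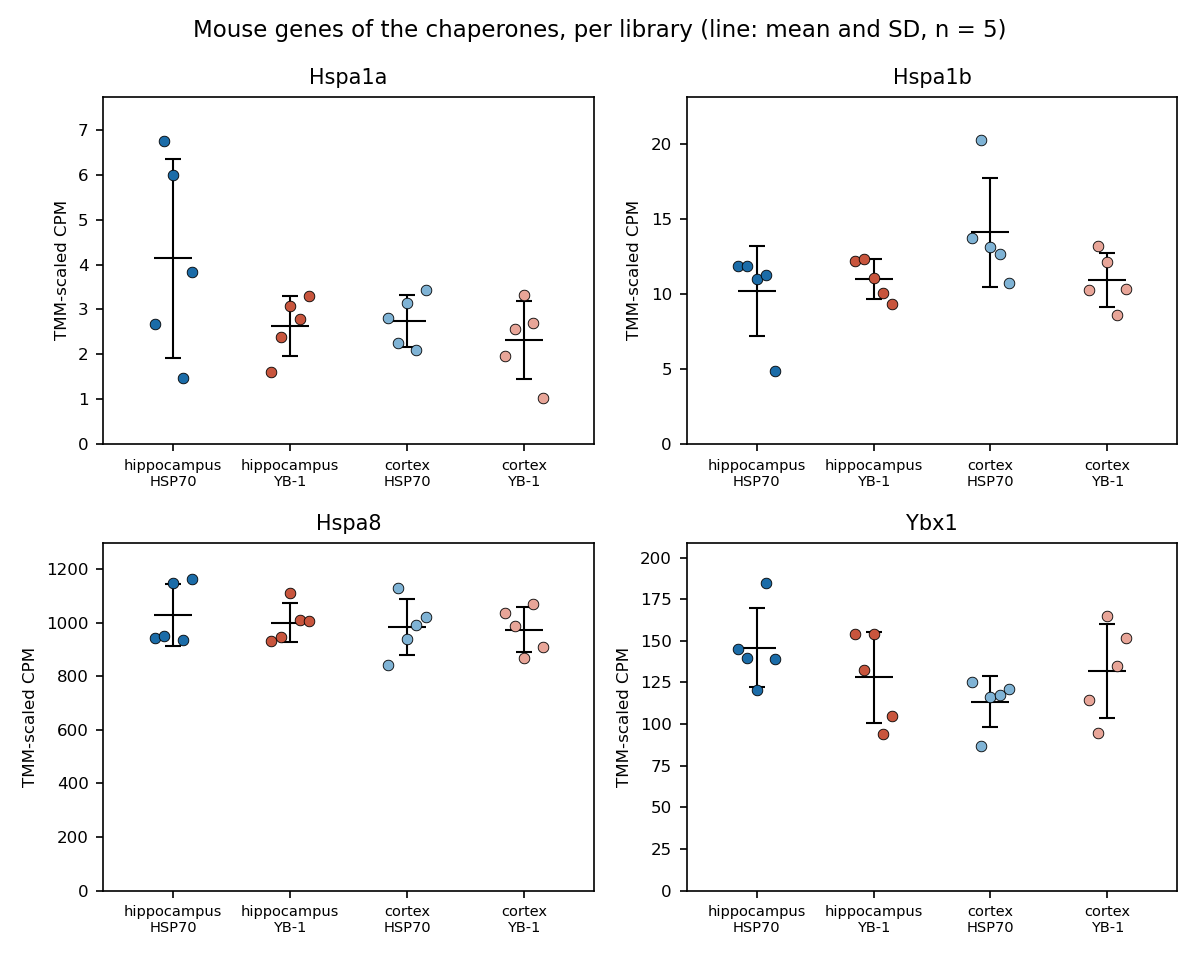
TMM-scaled CPM of Hspa1a, Hspa1b, Hspa8 and Ybx1 in each library, with 1 point per library and the mean and SD of each group of 5. The HSP70 and YB-1 points overlap in both tissues, for example Ybx1 at 146 ± 23.7 and 128 ± 27.6 CPM in the hippocampus.

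In the hippocampus, genes of the interferon response and of antigen presentation lay mostly on the higher side with YB-1 relative to HSP70, and markers of the meninges on the lower side. These lists passed camera with its preset correlation but not with an estimated correlation (adjusted p = 0.386, 0.427 and 0.091), and no single gene passed. All 25 measured interferon-stimulated genes had positive log2 fold changes, with a median of 0.70, and 12 of them had an unadjusted p under 0.05. Examples are Oas1a, an antiviral enzyme, at 0.85 ± 0.32, Ifih1, a sensor of viral RNA, at 0.87 ± 0.33, and Ifit3 at 0.72 ± 0.27 (log2 fold change ± SE). Of 21 genes of antigen presentation and complement, 7 of which are also in another list, 19 were on the higher side, with a median of 0.60. Among them were the peptide transporter gene Tap2 at 0.63 ± 0.14 and the class I genes H2-K1 at 0.66 ± 0.25 and H2-T23 at 0.74 ± 0.27. The level of H2-Eb1, an MHC class II gene, differed by animal in both tissues. Whether MHC haplotypes of these outbred mice bear on the antigen presentation list was not tested. All 16 measured markers of meningeal and perivascular fibroblasts were on the lower side, with a median of -0.34. They include Ptgds, which encodes a prostaglandin D synthase, at -0.70 ± 0.22, the anion transporter gene Slc22a6 at -0.79 ± 0.20 and Aebp1 at -0.61 ± 0.15.

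No single hippocampal gene passed the threshold. The quasi-likelihood test in edgeR called 0 of 13723 genes at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 329 (2.4%), below the share of 0.05 that no difference gives on average. Of the 329, 194 were higher and 135 lower with YB-1, and the smallest adjusted p was 1. DESeq2 also called 0 (518 at an unadjusted p under 0.05), as did limma-voom with quality weights (729). The genes with the smallest p on the higher side were Tap2, Gbp5, an interferon-induced GTPase (1.21 ± 0.28), Zfp811 (1.43 ± 0.34), the immunoglobulin segment Igkv4-57-1 (2.11 ± 0.52) and the adhesion receptor gene Adgre5 (0.86 ± 0.23). On the lower side they were Slc22a6, Aebp1, the myelin protein gene Pmp22 (-0.64 ± 0.18), the retinoic acid-binding protein gene Crabp2 (-1.40 ± 0.40) and Bace2 (-0.68 ± 0.20), a protease related to the β-secretase.

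Among 47 gene lists fixed before the data were examined, 16 passed camera in the hippocampus with its preset correlation, 13 higher and 3 lower with YB-1. None passed with an estimated correlation or with fry, and 10 of 100 splits of the 10 libraries gave at least 16 lists. With the preset correlation the adjusted p was 1.39e-20 for the interferon list, 2.92e-12 for antigen presentation and complement and 3.72e-10 for the meningeal markers. Adjusted over the list alone, 0 interferon genes, 1 antigen presentation gene and 5 meningeal genes passed. The mean interferon score was 3.78 ± 0.47 log2 CPM with HSP70 and 4.45 ± 0.45 with YB-1 (n = 5, exact permutation p = 0.0714, adjusted over 47 lists 0.839). For the meningeal markers the scores were 4.48 ± 0.23 and 4.11 ± 0.14 (n = 5, exact permutation p = 0.0238, adjusted 0.839).

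**Figure D3:**
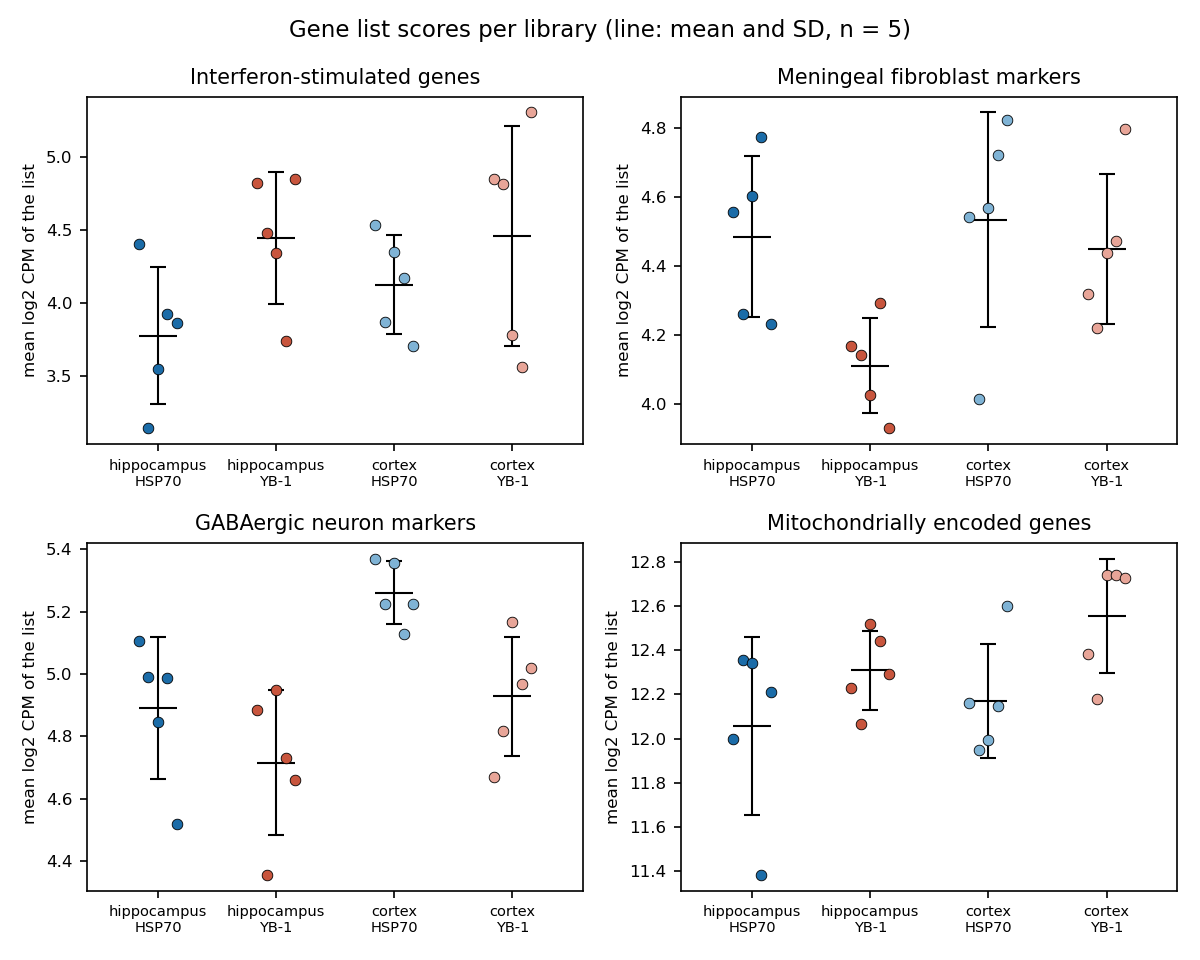
Mean log2 CPM of the members of 4 gene lists in each library, with 1 point per library and the mean and SD of each group of 5. The hippocampal interferon scores average 3.78 with HSP70 and 4.45 with YB-1, and the cortical scores of GABAergic neuron markers 5.26 and 4.93, with points of the treatments overlapping in both cases.

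Among the glial lists of the hippocampus, genes of reactive astrocytes had a median log2 fold change of 0.33, with 15 of 19 on the higher side. Psmb8 was at 0.60 ± 0.25, Gbp2 at 0.76 ± 0.32 and the oncostatin M receptor gene Osmr at 0.84 ± 0.36. Of the 20 genes listed, 9 are also in another list, Gbp2 in the interferon list and Psmb8 in that of antigen presentation. The list had an adjusted p of 5.19e-05 in camera (adjusted p = 0.555 with an estimated correlation). Of 22 myelin genes 20 were on the lower side, with a median of -0.21, for example Car2 at -0.39 ± 0.13 and Apod at -0.47 ± 0.20. Their adjusted p was 5.52e-05 (adjusted p = 0.555 with an estimated correlation), and 0.172 without replicate 4 of the HSP70 group. Markers of resting microglia were higher in 18 of 20 cases by a median of 0.18 (adjusted p = 0.00207, and 0.575 with an estimated correlation), and the call ended without any of replicates 2 and 5 of the HSP70 group and 1 and 5 of the YB-1 group (0.0578 to 0.0871). C1qc was at 0.56 ± 0.24 and P2ry13 at 0.46 ± 0.21, while Fcrls was at -1.41 ± 0.46. Genes of activated microglia, such as Cst7 (1.06 ± 0.47), Ctsz (0.39 ± 0.17) and Gpnmb (0.72 ± 0.34, and 0.33 without replicate 1 of the YB-1 group), had a median of 0.12 and an adjusted p of 0.0425 (adjusted p = 0.555 with an estimated correlation). That call ended without any of replicates 1, 2, 3 and 5 of either group (0.054 to 0.309). The general astrocyte list, with a median of -0.09, did not pass (adjusted p = 0.0551), but did without any of replicates 3 and 5 of the HSP70 group and 1 and 3 of the YB-1 group (0.00555 to 0.0317). Its members with the smallest p were Ntsr2 (-0.24 ± 0.13), Fgfr3 (-0.22 ± 0.13) and Sox9 (0.26 ± 0.21).

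Among the neuronal lists of the hippocampus, markers of GABAergic neurons had a median of -0.17, with 14 of 18 on the lower side, including somatostatin (Sst, -0.46 ± 0.17), Tac1 (-0.71 ± 0.33) and Dlx2 (-0.48 ± 0.25). Markers of dentate granule cells were higher in 12 of 13 cases by a median of 0.21, for example Lct (0.70 ± 0.23), Dsp (0.99 ± 0.38) and Il16 (0.34 ± 0.16). Postsynaptic genes were higher by a median of 0.14, with Grin2b at 0.42 ± 0.25 (0.17 without replicate 4 of the YB-1 group), Shank1 at 0.24 ± 0.14 and Camk2a at 0.20 ± 0.13. The camera adjusted p was 0.00216 for the GABAergic, 0.00288 for the dentate and 0.029 for the postsynaptic list, and adjusted p = 0.497, 0.427 and 0.575, respectively, with an estimated correlation. The GABAergic call ended without replicate 1 of the HSP70 group (0.0555) or 2 of the YB-1 group (0.086), and the postsynaptic call without any of replicates 3, 4 and 5 of the HSP70 group and 1 and 5 of the YB-1 group (0.108 to 0.357). Activity-induced immediate early genes did not pass (median -0.10, adjusted p = 0.0777), but did without replicate 4 of the HSP70 group (0.0428) or 2 of the YB-1 group (0.0018). Dusp1, Npas4 and Klf4 were at -0.30 ± 0.16, -0.83 ± 0.53 and -0.64 ± 0.40.

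Of the other hippocampal lists, inflammatory mediators (median 0.25, adjusted p = 0.00494) included the chemokine genes Ccl12 at 1.72 ± 0.66 and Cxcl10 at 1.53 ± 0.67 (0.59 without replicate 3 of the YB-1 group), and the cytokine gene Il33 at -0.41 ± 0.20. Endothelial markers had a median of 0.17 (adjusted p = 0.00494), with Ly6a at 0.66 ± 0.22, Cdh5 at 0.39 ± 0.27 and Ly6c1 at 0.25 ± 0.17. Genes of the mitochondrial genome were at a median of 0.32 (adjusted p = 0.00187), with mt-Nd6 at 0.42 ± 0.19, mt-Nd5 at 0.32 ± 0.16 and mt-Nd1 at 0.38 ± 0.21. Proteasome subunits, for example Psmb2, Psmc1 and Psmc2, had a median of 0.11 (adjusted p = 0.0158), and ribosomal proteins, for example Rps18, Rpl3 and Rpl30, a median of 0.08 (adjusted p = 0.0405). With an estimated correlation the adjusted p of these lists was 0.497, 0.521, 0.555, 0.656 and 0.809. The inflammatory call ended without replicate 2 of the HSP70 group (0.107), the endothelial call without its replicate 2 (0.0602) or 5 (0.125), and the mitochondrial call without replicate 4 of the HSP70 (0.0673) or the YB-1 group (0.0799). Without any of replicates 1, 2 and 4 of the HSP70 group and 2 and 4 of the YB-1 group, the proteasome (0.054 to 0.922) and ribosomal (0.172 to 0.849) calls ended. Choroid plexus markers, for example Prlr at 0.89 ± 0.43, F5 at 0.48 ± 0.51 and Kl at 0.27 ± 0.62, had a median of 0.13 and an adjusted p of 3.83e-05 (adjusted p = 0.575 with an estimated correlation), and 0.0555 and 0.0577 without replicate 1 of the HSP70 and 2 of the YB-1 group. Their mean score was 2.72 ± 1.93 log2 CPM with HSP70 and 3.50 ± 1.23 with YB-1 (n = 5, exact permutation p = 0.468). The scores thus varied more within treatments than between them. Ttr, a gene of the choroid plexus, ranged from 24.6 to 1260 CPM with HSP70 and from 106 to 720 CPM with YB-1. Whether differing amounts of choroid plexus in the samples account for this was not tested.

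The lists closest to the treatments and the disease model did not pass in the hippocampus. Heat shock proteins and co-chaperones had an adjusted p of 0.937, a median of -0.03 and a test that pointed higher, with Hspe1 at 0.48 ± 0.19, Hsp90aa1 at 0.38 ± 0.21 and Bag3 at 0.23 ± 0.14. The YB-1 paralogues and RNA-granule proteins, with Hnrnpa2b1 at 0.24 ± 0.18, had an adjusted p of 0.293, and 0.0102 without replicate 1 of the HSP70 group. Genes tied to amyloid, tau and Alzheimer's disease risk, with Cd33 at 0.48 ± 0.37 and Aph1a at -0.25 ± 0.20, had a median of 0.0010 and an adjusted p of 0.937.

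The hippocampal log2 fold changes of several genes named above moved by over 1.5 times without 1 library. Without HSP70 replicate 1, Npas4 was at -0.24, Hnrnpa2b1 at 0.42, Sox9 at 0.42 and Ly6c1 at 0.15, and without HSP70 replicate 2, Hspa1a was at -0.38. Without HSP70 replicate 3, F5 was at 0.23 and Sox9 at 0.15. Without HSP70 replicate 4, Ybx1 was at -0.084, Apod at -0.25, mt-Nd5 at 0.19, mt-Nd1 at 0.21 and Aph1a at -0.17. Without HSP70 replicate 5, Prlr was at 1.56, F5 at 0.95, Klf4 at -0.40, Ly6c1 at 0.40, Cdh5 at 0.23, Hnrnpa2b1 at 0.14 and Aph1a at -0.15. Omitting YB-1 replicate 1 left Gbp2 at 0.51, Osmr at 0.48 and Sox9 at 0.14, and omitting YB-1 replicate 2 left Dsp at 0.48, F5 at 0.13 and Camk2a at 0.13. Omitting YB-1 replicate 3 left Tac1 at -1.06. Omitting YB-1 replicate 4 left Hspe1 at 0.26, Hsp90aa1 at 0.14, mt-Nd6 at 0.20 and Ybx1 at -0.093, and omitting YB-1 replicate 5 left Npas4 at -0.54, Cd33 at 0.22 and Ybx1 at -0.12.

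In the cortex, genes of reactive astrocytes and of the interferon response lay mostly on the higher side with YB-1, and markers of GABAergic neurons and immediate early genes on the lower side. These lists passed camera with its preset correlation but not with an estimated correlation (adjusted p = 0.572, 0.622, 0.557 and 0.572), and no single gene passed edgeR's test. Since depth did not overlap between the cortical treatments, a separate preparation or sequencing of them cannot be told apart from the treatment. This limit holds for every cortical comparison of treatments and for the interaction, and depth was not evened out for these tests. Of 19 reactive astrocyte genes 17 were on the higher side, with a median log2 fold change of 0.53. Among them were Serpina3n at 0.93 ± 0.26 and the complement inhibitor gene Serping1 at 0.66 ± 0.22. Gfap, the astrocyte intermediate filament, was at 934 ± 181 CPM with HSP70 and 1312 ± 284 CPM with YB-1 (n = 5). All 25 interferon-stimulated genes were again on the higher side, with a median of 0.49, for example Stat2 (0.56 ± 0.21), Ifitm3 (0.55 ± 0.21) and Lgals3bp (0.52 ± 0.19). Of 18 GABAergic neuron markers 17 were on the lower side, with a median of -0.30. They include the neuropeptide genes Vip (-0.83 ± 0.18) and Sst (-0.51 ± 0.15) and the GABA-synthesising enzyme Gad1 (-0.51 ± 0.18). Of 23 immediate early genes 20 were on the lower side, with a median of -0.25, for example Btg2 (-0.70 ± 0.26), Ccn1 (-0.74 ± 0.29) and Dusp6 (-0.41 ± 0.19).

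Single cortical genes did not pass edgeR's quasi-likelihood test, which called 0 of 14114 genes, with a smallest adjusted p of 0.25. At an unadjusted p under 0.05 there were 774 (5.48%), 426 higher and 348 lower. No difference would give a share of 0.05 on average. On the higher side the smallest p belonged to the immunoglobulin segment Igkv12-38 (3.47 ± 0.60), Il1rn, the interleukin-1 receptor antagonist (2.49 ± 0.52), Gpnmb, a glycoprotein of activated microglia (1.05 ± 0.22), Tnfaip2 (1.59 ± 0.38) and Hcar2, a receptor for niacin and ketone bodies (1.36 ± 0.33). Il1rn was at 0.56 ± 0.49 CPM with HSP70 and 3.14 ± 1.39 CPM with YB-1, and Gpnmb at 6.75 ± 1.32 and 13.7 ± 3.88 CPM (n = 5). On the lower side stood Vip, at 25.2 ± 5.41 and 13.9 ± 1.61 CPM, the respiratory chain genes Cox7a2l (-0.57 ± 0.14) and Cox5a (-0.73 ± 0.18), Irak1bp1 (-1.10 ± 0.27) and Rassf3 (-0.78 ± 0.19). DESeq2 called 4 genes, Il1rn, Gpnmb, Igkv12-38 and Vip (1080 at an unadjusted p under 0.05), and limma-voom with quality weights called 1, Igkv12-38 (1003). With log2 Bc1 share as a covariate, a setting chosen after the data were seen, edgeR called 273 genes, and 0 without replicate 1 of the cortical HSP70 group.

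Camera called 11 of 47 lists in the cortex, 9 higher and 2 lower with YB-1, and 7 without replicate 5 of the YB-1 group. No list passed with an estimated correlation or with fry, and 37 of 100 splits of the cortical libraries gave at least 11 lists. With the preset correlation the adjusted p was 2.32e-07 for both the reactive astrocyte and the interferon list, 4.67e-07 for the GABAergic markers and 4.58e-05 for the immediate early genes. Adjusted over the list alone, 1 reactive astrocyte gene, 0 interferon genes, 2 GABAergic markers and 0 immediate early genes passed. The mean score of the GABAergic markers was 5.26 ± 0.10 log2 CPM with HSP70 and 4.93 ± 0.19 with YB-1 (n = 5, exact permutation p = 0.0159, adjusted 0.497). The interferon score was 4.13 ± 0.34 with HSP70 and 4.46 ± 0.75 with YB-1 (n = 5, exact permutation p = 0.381, adjusted 0.705).

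Genes of the mitochondrial genome had a median log2 fold change of 0.47 in the cortex, with 8 of 9 on the higher side, for example mt-Nd5 at 0.69 ± 0.21, mt-Nd2 at 0.57 ± 0.18 and mt-Cytb at 0.53 ± 0.19. Their adjusted p was 2.65e-06 (adjusted p = 0.557 with an estimated correlation), and 4 passed adjusted over the list alone. Genes of antigen presentation and complement, for example C4b (0.60 ± 0.21) and Tap1 (0.88 ± 0.31), had a median of 0.52 and an adjusted p of 4.2e-06 (adjusted p = 0.622 with an estimated correlation). Whether MHC haplotypes bear on that list was not tested in the cortex either. Resting microglia markers, with Tyrobp at 0.43 ± 0.19, Csf1r at 0.35 ± 0.16 and Trem2 at 0.41 ± 0.20, had a median of 0.26 (adjusted p = 0.000456, and 0.622 with an estimated correlation). Activated microglia genes, with Axl at 0.32 ± 0.13, had one of 0.21 (adjusted p = 0.000657, and 0.572 with an estimated correlation). Without replicate 5 of the YB-1 group these microglial lists had an adjusted p of 0.199 and 0.0638, and the inflammatory mediators 0.178. Inflammatory mediators, with Relb at 0.66 ± 0.21, Icam1 at 0.73 ± 0.24 and Ccl12 at 1.14 ± 0.47, had a median of 0.30 (adjusted p = 0.00709, and 0.572 with an estimated correlation). Oligodendrocyte precursor markers, with Enpp6 at 0.98 ± 0.37, Bcas1 at 0.25 ± 0.14 and Tnr at 0.29 ± 0.18, had a median of 0.21 (adjusted p = 0.0296, and 0.557 with an estimated correlation). Their call ended without replicate 1 of the HSP70 group (0.106) and without replicate 3 (0.231) or 5 (0.055) of the YB-1 group. Ribosomal proteins, with Rpl30 at 0.77 ± 0.26 and Rpl32 at 0.32 ± 0.17, had one of 0.07 (adjusted p = 0.0091, and 0.885 with an estimated correlation), and did not pass without any of replicates 1 and 3 of the HSP70 group and 2 and 4 of the YB-1 group (0.0652 to 0.662).

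Heat shock proteins and co-chaperones did not pass in the cortex (median -0.09, adjusted p = 0.27), with Chordc1 at -0.55 ± 0.22, Hspb1 at -0.54 ± 0.22 and Dnaja1 at -0.42 ± 0.18. Neither did the YB-1 paralogues and RNA-granule proteins (median -0.14, adjusted p = 0.271), with Tial1 at -0.38 ± 0.21, nor the Alzheimer's disease genes (median -0.05, adjusted p = 0.726), with Gsk3b at -0.38 ± 0.21 and Aph1a at 0.23 ± 0.16. Myelin genes had a median of 0.10 (adjusted p = 0.254), with Myrf at 0.51 ± 0.18, Ugt8a at -0.59 ± 0.22 and Sox10 at 0.47 ± 0.23. The astrocyte list had a median of -0.06 (adjusted p = 0.356, and 0.0484 without replicate 3 of the YB-1 group), with Gjb6 at -0.27 ± 0.15 and Acsl3 at -0.29 ± 0.19. Choroid plexus markers, with Lbp at 0.87 ± 0.31, Folr1 at -1.68 ± 0.82 (-0.41 without replicate 4 of the HSP70 group) and Aqp1 at 0.91 ± 0.49, had a median of -0.27, a test that pointed higher and an adjusted p of 0.738.

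Cortical log2 fold changes of named genes moved likewise without 1 library. Without HSP70 replicate 1, Gad1 was at -0.33, Btg2 at -0.43, Dnaja1 at -0.24, Gsk3b at -0.17, Acsl3 at -0.18, Sox10 at 0.30, Bcas1 at 0.15 and Aph1a at 0.14. Without HSP70 replicate 2, Hspa1b was at -0.17, without HSP70 replicate 4, Aqp1 was at 1.41, and without HSP70 replicate 5, Hspa1a and Gjb6 were at -0.14 each. Omitting YB-1 replicate 3 left Hspa1a at -0.41, Ybx1 at 0.16 and Tnr at 0.15, and omitting YB-1 replicate 4 left Tial1 and Gsk3b at -0.25 each and Acsl3 at -0.15. Omitting YB-1 replicate 5 left Serping1 at 0.43, Trem2 at 0.24, Aqp1 at 0.56 and Hspa1a at -0.0355.

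Whether the tissues differed in their treatment difference was tested directly. No gene passed. The quasi-likelihood test of the interaction in edgeR called 0 of 14616 genes, with 227 (1.55%) at an unadjusted p under 0.05. No difference would give a share of 0.05 on average. DESeq2 (446) and limma-voom (316 at an unadjusted p under 0.05) also called 0. Among the gene lists, 8 passed camera and none passed with an estimated correlation or fry, and 32 of 100 splits gave at least 8. Myelin genes and meningeal markers stood lower with YB-1 in the hippocampus relative to the cortex, by medians of -0.34 and -0.35 (adjusted p = 3.76e-05 for each, and 0.818 and 0.463 with an estimated correlation). Precursor cell markers (median -0.25, adjusted p = 0.00779) and striatal markers (median -0.44, adjusted p = 0.0392) pointed the same way, with an adjusted p of 0.381 and 0.818 with an estimated correlation. The striatal score stood apart in replicate 4 of the cortical YB-1 group, where the SD was 0.59 log2 CPM against 0.081 with HSP70. Without that library the camera adjusted p of the striatal list was 0.249. Relatively higher in the hippocampus were choroid plexus markers (median 0.53, adjusted p = 0.00509), nuclear noncoding RNAs (median 0.30, adjusted p = 0.0392), immediate early genes (median 0.15, adjusted p = 0.0392) and interferon-stimulated genes (median 0.20, adjusted p = 0.0415). With an estimated correlation the adjusted p of these was 0.822, 0.818, 0.822 and 0.822. Leaving out 1 library ended the meningeal call in 0 of 20 cases, myelin in 1, precursor markers in 2, choroid plexus in 4, striatal markers and nuclear noncoding RNAs in 9 each, interferon in 10 and immediate early genes in 12. With each animal as a block, 12 lists passed, and the interferon list had an adjusted p of 0.00369.

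Across 13483 genes tested in both tissues, the treatment differences of hippocampus and cortex correlated with Pearson's r = 0.312 and Spearman's rho = 0.216, with 56.7% of genes on the same side (genes are not independent replicates). At an unadjusted p under 0.05 in both tissues, 58 genes were higher with YB-1 in both, against 5.7 for independent lists, and 12 were lower in both, against 3.2. The higher genes include Gbp5, Stat2, H2-K1, Il1rn and the inflammasome adaptor gene Pycard, and the lower ones Sst and Cartpt, chosen here after their values were seen. Same-numbered hippocampal and cortical libraries of a treatment deviated together and were taken to come from 1 animal, and shared animals alone correlate the differences. On mean log2 CPM the observed r was 0.288, and 59 of the 126 splits of the 10 animals gave an r at least as large, with a median of 0.264. Over the 10 animals, the interferon scores of the tissues correlated with Pearson's r = 0.725 (permutation p = 0.0192) and Spearman's rho = 0.745 (permutation p = 0.0173), and with r = 0.634 without the 2 animals farthest from the median. For log2 immunoglobulin CPM, r was 0.803 (permutation p = 0.004) and rho 0.806 (permutation p = 0.00704), with r = 0.734 without 2 animals.

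**Figure D4:**
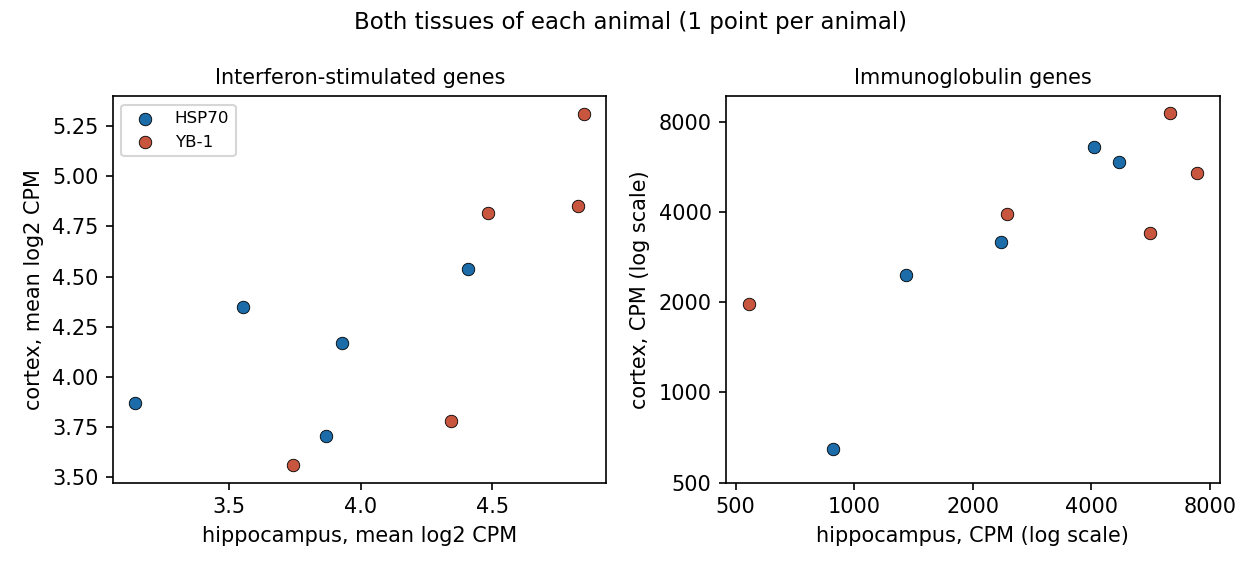
Interferon scores as mean log2 CPM (left) and immunoglobulin transcripts as CPM on log axes (right), with the hippocampus on the horizontal and the cortex on the vertical axis and 1 point per animal, coloured by treatment. Pearson's r over the 10 animals is 0.725 for the interferon score and 0.803 for immunoglobulin, whose values range from 539.5 to 8568 CPM.

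The comparison of tissues shows the scale of a regional difference in these libraries. Of 14616 genes, 2320 passed edgeR's quasi-likelihood test, 1250 higher and 1070 lower in the hippocampus than in the cortex. Cabp7, a calcium-binding protein of hippocampal pyramidal cells, was at 171 ± 37.9 CPM in the hippocampus and 14.5 ± 2.66 CPM in the cortex of HSP70-treated animals (n = 5). Its log2 fold change over both treatments was 3.50 ± 0.13 (adjusted p = 3.98e-15). Olfml2b (2.37 ± 0.12), Doc2b (2.40 ± 0.13), Lct (3.48 ± 0.19), Galnt17 (1.37 ± 0.08), and the hippocampal markers C1ql2 (3.66 ± 0.21) and Fibcd1 (3.18 ± 0.19) were also higher. Lower in the hippocampus were Cux2 (-1.87 ± 0.08) and Lamp5 (-2.22 ± 0.12), markers of upper cortical layers, Rasgef1c (-2.47 ± 0.12), Camk2n1, an inhibitor of calcium/calmodulin kinase (-1.86 ± 0.10), and Stx1a, a presynaptic syntaxin (-1.55 ± 0.10). Of the deep-layer markers, Tbr1 was lower (-1.52 ± 0.13) and Crym higher (1.89 ± 0.13).

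Of 47 lists, 14 passed camera between the tissues, and 6 of them with an estimated correlation. Myelin genes (median 1.16, 20 of 22 passing and higher in the hippocampus, adjusted p = 4.46e-25) and upper-layer markers (median -1.18, 12 of 14 passing and lower, adjusted p = 7.32e-14) were among the 6. The others were pyramidal markers of the hippocampus (median 0.73, adjusted p = 4.98e-08), presynaptic genes (median -0.28, adjusted p = 8.51e-08), clock genes (median -0.31, adjusted p = 1.02e-05) and precursor cell markers (median 0.26, adjusted p = 0.0016). The adjusted p of the 6 in this order was, with an estimated correlation, 0.00721, 0.000801, 0.000801, 0.0444, 0.00721 and 0.0444. Choroid plexus markers had a median of 3.40 with 18 of 18 members passing and higher in the hippocampus, ependymal markers one of 1.12, and thalamic and habenular markers one of 1.09 (adjusted p = 0.321, 0.111 and 0.369 with an estimated correlation). These lists were included to show neighbouring tissue taken along at dissection. Their levels therefore need not be those of hippocampal cells, and the amount of such tissue was not measured. Immediate early genes were at a median of -0.57 (adjusted p = 0.000192, and 0.317 with an estimated correlation).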

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

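The tests of immunoglobulin and chromosome 17 for the interferon list, of the meningeal markers, of Bc1 against treatment and of all splits of the libraries were chosen only after the results were seen. Those of Bc1 against transcript length and depth, and of the thinned, length and single-library counts with Bc1 as a covariate, were written before.

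The interferon list stood higher with YB-1 in both tissues, and its treatment difference was greater in the hippocampus than in the cortex (adjusted p = 0.0415 in camera, and 0.822 with an estimated correlation), a call that ended without any of 10 libraries (0.0969 to 0.853): replicates 2 and 3 of the hippocampal HSP70, 1, 2 and 5 of the hippocampal YB-1, 1, 3 and 4 of the cortical HSP70 and 3 and 4 of the cortical YB-1 group. A haplotype that acts only on genes of chromosome 17, which holds the MHC, cannot raise this list. All 25 members lie outside that chromosome and were higher, with medians of 0.70 in the hippocampus and 0.49 in the cortex. Differing MHC haplotypes of these outbred mice that act on genes elsewhere stay open. The test on members outside chromosome 17 cannot decide that, since it has no members inside to compare. Antibody-secreting cells that differ between animals stay open too: with log2 immunoglobulin CPM as a covariate the score difference was 0.516 in the hippocampus (95% interval 0.085 to 0.946, 0.670 without the covariate) and 0.157 in the cortex (-0.586 to 0.899, 0.336 without it). An accident of which animals fell into which treatment cannot be excluded either. The interferon score had an exact permutation p of 0.0714 in the hippocampus and 0.381 in the cortex (n = 5, adjusted over 47 lists 0.839 and 0.705). Counts of all passing lists do not single out this list. At least the 16 lists of the hippocampus came in 10 of 100 splits (highest other 20). For the 11 of the cortex it was 37 (highest other 18) and for the 8 of the interaction 32 (highest other 13). A treatment effect remains possible beside these, and may be read as more with YB-1 or less with HSP70.

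Meningeal fibroblast markers stood lower with YB-1 in the hippocampus and relative to the cortex (adjusted p = 3.76e-05 in camera for the latter, and 0.463 with an estimated correlation). Less meninges left on the YB-1 samples at dissection stays open: the 5 most abundant members, Ptgds (-0.70), Igfbp2 (-0.24), Ccn3 (-0.26), Fmod (-0.71) and Col1a2 (-0.44), had a median of -0.44, but with all 16 measured members lower this does not separate it from a change within these cells. Less vascular tissue of every kind would put the endothelial and mural lists lower with YB-1, but neither lay lower, with medians of 0.17 and 0.0359. Relative to the meningeal score their scores were higher with YB-1 by 0.580 and 0.377 (n = 5, exact permutation p = 0.0317 and 0.0556, adjusted 0.0556 for both). The directions thus go against this explanation, while the spread between libraries does not settle it. Among the 18 listed markers some are also made within brain tissue, such as Ptgds in oligodendrocytes, and the myelin list too lay on the lower side in the hippocampus (adjusted p = 5.52e-05, 0.555 with an estimated correlation and 0.172 without replicate 4 of the HSP70 group). A change of these cells with the treatment stays open and untested.

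Bc1 took 3.92% to 20.8% of reads, and its log2 share in replicate 1 of the cortical HSP70 group stood apart (gap over range 0.760). Libraries rich in Bc1 were rich in other short transcripts, with r across genes of -0.352 in the hippocampus and -0.286 in the cortex between a gene's slope on Bc1 and its transcript length, which is consistent with a preparation that favoured short molecules in some libraries. Depth (r = 0.000 in the hippocampus, 0.193 in the cortex) and treatment (exact permutation p = 0.976 and 0.365) cannot be told from no relation with 10 libraries a tissue. With Bc1 as a covariate, 273 cortical genes passed and 1 of 100 splits, the real one, gave as many (highest other 72), while 0 hippocampal genes passed, a count that any split reaches (100 of 100, highest other 66) and that tests nothing. The depth gap between the cortical treatments does not account for the 273, since 196 passed with every library thinned to 6414215 reads, but 0 passed without that replicate 1, a length trend (r = -0.230) stays open, and a separate preparation of the cortical treatments cannot be told apart from the treatment.

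Further lists passed camera for a treatment difference that depends on the tissue, and none of them with an estimated correlation: myelin genes (adjusted p = 3.76e-05, and 0.818 with an estimated correlation), oligodendrocyte precursor markers (0.00779 and 0.381), choroid plexus markers (0.00509 and 0.822), striatal markers and nuclear noncoding RNAs (0.0392 and 0.818 each) and immediate early genes (0.0392 and 0.822). The myelin and precursor calls ended without replicate 4 of the hippocampal HSP70 group (0.0552 and 0.063), and the precursor call also without replicate 3 of the cortical YB-1 group (0.0567). The choroid plexus call ended without any of 4 libraries (0.113 to 0.163), replicates 1 and 3 of the hippocampal HSP70, 2 of the hippocampal YB-1 and 4 of the cortical HSP70 group. The striatal call ended without any of 9 (0.0595 to 0.249), replicates 3, 4 and 5 of both HSP70 groups, 2 of the hippocampal YB-1 and 3 and 4 of the cortical YB-1 group. The call of nuclear noncoding RNAs ended without any of 9 (0.0593 to 0.202), replicates 3, 4 and 5 of the hippocampal HSP70, 1 and 2 of the hippocampal YB-1, 1, 3 and 5 of the cortical HSP70 and 4 of the cortical YB-1 group. That of immediate early genes ended without any of 12 (0.0557 to 0.284), replicates 2 to 5 of the hippocampal HSP70, 1 and 2 of the hippocampal YB-1, 1 and 2 of the cortical HSP70 and 1, 3, 4 and 5 of the cortical YB-1 group.

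Within groups of 5, a library was singled out where its gap to the next, divided by the range, exceeded 0.710; this held for 31 of 414 groups checked (7.49%), where chance gives about 1 in 20. Replicate 1 of the cortical HSP70 group stood apart in Gad1 (0.752), Btg2 (0.794), Dnaja1 (0.755), Gsk3b (0.747), Fibcd1 (0.776) and the postsynaptic score (0.779), replicate 2 in Ybx1 (0.800), Serping1 (0.888) and Galnt17 (0.883), and replicate 5 in mt-Nd2 (0.825). In the cortical YB-1 group these were replicate 4 for Chordc1 (0.858), Tial1 (0.747) and the striatal score (0.773), replicate 2 for Gjb6 (0.721) and the immediate early score (0.784), and replicate 5 for Axl (0.731). Replicate 5 of the hippocampal HSP70 group stood apart in Hspa1b (0.915), Cdh5 (0.764), Prlr (0.842) and the number of genes detected (0.790), replicate 1 in Npas4 (0.741), replicate 2 in Psmb8 (0.766) and replicate 4 in Car2 (0.773). In the hippocampal YB-1 group replicate 4 did so in Grin2b (0.770), Hspe1 (0.778) and the endothelial score (0.767), replicate 3 in Tap2 (0.717) and Cabp7 (0.713), replicate 5 in Npas4 (0.822) and replicate 1 in Rasgef1c (0.882).

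For single genes between treatments the real count was 0, which any split reaches (100 of 100), so that these splits test nothing; they gave up to 463 genes in another split of the hippocampal libraries and 20 in the cortical ones, and at most 0 for the interaction. Any gene passed in 7 of the hippocampal splits, with a median of 0, and counts of 463, 447 and 107 in 3 of them point to a structure among these libraries that was not identified. At an unadjusted p under 0.05, 57 splits reached the 329 hippocampal genes (highest other 3364) and 26 the 774 cortical genes (highest other 3633). Between tissues only the real one of 100 splits reached the 2320 genes (highest other 1). When tissues were exchanged within animals, again only the real one of 100 did (highest other 1130). With 100 splits this share cannot fall below 1 in 100. The count of 14 lists does not judge the lists, since 31 splits reached it and the other splits had a median of 11 (highest other 24). With an estimated correlation 6 lists passed between tissues, and with fry 17. For the correlation of the tissues' treatment differences, 59 of 126 splits reached the real value (highest other 0.644).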

How the results depend on the processing

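The Bc1 covariate, the average over tissues and the omission of 2 libraries were chosen only after the data were seen; the other alternatives were fixed before. Hippocampal genes stayed at 0 in all 22 alternatives (209 to 1105 at an unadjusted p under 0.05) and the interaction at 0 in all 29 (185 to 1194). Between tissues 2080 to 2888 genes passed, the most with the animal as a block, against 2320, with 2800 in DESeq2 and 2854 in limma-voom. In the cortex 16 of 22 alternatives gave 0 genes. The others gave 9 with no low-count filter (Il1rn, Hcar2, Ubl3, Gpnmb, Igkv12-38, Vwf, Vip, Cox5a and Tnfaip2), 4 in DESeq2, 1 in limma-voom with quality weights, 1 with a surrogate variable (Il1rn), 273 with the Bc1 covariate and, leaving out each library, 0 to 1 (Igkv12-38 without replicate 3 of the HSP70 group); the cause was not tested.

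Lists past the threshold went from 16 in the hippocampus, 11 in the cortex and 8 in the interaction to 0, 0 and 0 with an estimated correlation in camera. In fry they were also 0, 0 and 0. Between tissues they went from 14 to 6 with an estimated correlation and to 17 in fry. Leaving out each library gave 12 to 18, 7 to 14, 3 to 13 and 14 to 17 lists. The 7 came without replicate 5 of the cortical YB-1 group; in the interaction 3 lists passed without replicate 3 and 5 without replicate 4 of the hippocampal HSP70 group, 5 without replicate 2 and 13 without replicate 4 of the hippocampal YB-1 group, and 5 without replicate 4 of the cortical HSP70 group. The replicate number as a block gave 17 and 14 lists in the hippocampus and cortex and 0 genes in each (256 and 858 at an unadjusted p under 0.05), though these numbers do not pair the treatments and only 1 and 0 of 5 libraries correlated best with their own number. With the animal as a block, 0 interaction genes (409 at an unadjusted p under 0.05), 12 interaction lists and 15 tissue lists passed. That block brought in the postsynaptic (adjusted p = 0.00896), RNA-granule (0.0179), ependymal (0.0309) and antigen presentation (0.0391) lists for the interaction and resting microglia (0.0119) between tissues, and ended no call.

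Some directions turned, and the cause was not tested; an average over tissues mixes in the other tissue. In the hippocampus Hspa1b (log2 fold change 0.12) was at -0.0191 in limma-voom and -0.0868 averaged over tissues, Hspa8 (-0.03) at 0.0115 in limma-voom, and Ybx1 and Aph1a at 0.02 and 0.0081 averaged over tissues. In the cortex Hspa8 (0.01) was at -0.0033 with upper-quartile scaling, -0.0156 with no low-count filter, -0.0125 in limma-voom, -0.0442 with a surrogate variable and -0.0031 averaged over tissues, and Folr1 (-1.68) at 0.0069 averaged over tissues. The heat shock list turned lower in the hippocampus with the replicate block (adjusted p = 0.976) and the choroid plexus list in the cortex with the Bc1 covariate (0.988). Leaving out each library moved the log2 fold change of 36 of 73 hippocampal and 20 of 59 cortical genes of the naming rule by over 1.5 times, and it ranged from -0.0505 to 0.18 for Hspa1b, -0.0631 to 0.0253 for Hspa8 and -0.16 to 0.66 for Kl in the hippocampus, and from -0.0449 to 0.0689 for Hspa8 in the cortex. The adjusted p of lists that turned ranged, in the hippocampus, from 3.28e-09 to 0.849 for ribosomal proteins, 0.000127 to 0.922 for proteasome subunits, 0.659 to 0.948 for heat shock proteins, 0.0102 to 0.862 for RNA-granule proteins and 0.422 to 0.976 for Alzheimer's disease genes. In the cortex it ranged from 0.059 to 0.923 for RNA-granule proteins and 0.0641 to 0.918 for choroid plexus markers, in the interaction from 0.276 to 0.994 for resting microglia and 0.315 to 0.966 for astrocytes, and between tissues from 0.628 to 0.967 for RNA-granule proteins. No call of the interferon, antigen presentation, meningeal or dentate list in the hippocampus, nor of the interferon, reactive astrocyte, GABAergic, immediate early or mitochondrial list in the cortex, was lost without a library.

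The correlation of the tissues' treatment differences (0.312) was 0.386 for genes of at least 5 CPM, 0.311 with RLE scaling, 0.303 with blocks and 0.190 to 0.408 without each library. At the depth and spread of these libraries, which were not varied apart, the simulated designs recovered 56.7% of genes changed 2-fold in the hippocampus and 64.2% in the cortex but 11.9% of those changed 1.5-fold in each, so differences of that size can be missed.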

Other observations

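The tests of immunoglobulin transcripts and interferon scores across the tissues of an animal were chosen only after the values were seen, as were the genes named in the next paragraph.

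H2-Eb1 and Gdpd3 were high or low by animal, alike in both tissues of the animal. H2-Eb1, an MHC class II gene, was at 223 CPM in the hippocampus and 396 CPM in the cortex of HSP70 replicate 2, at 219 and 569 CPM in HSP70 replicate 3 and at 288 and 424 CPM in YB-1 replicate 4, while the other hippocampal libraries held 9 to 32.9 CPM and the other cortical ones 14.5 to 42.9 CPM. Gdpd3, a phosphodiesterase gene, was at 0 to 0.541 CPM in both tissues of HSP70 replicates 1, 2 and 3 and of YB-1 replicate 4, and at 8.66 to 41.1 CPM in the other animals. Drd2, a dopamine receptor gene of the striatum, stood at 50.6 CPM in the cortical library of YB-1 replicate 4 and at 1.9 to 6.62 CPM in the other cortical libraries, while the hippocampal library of that animal, at 8.35 CPM, lay within the 4.38 to 18.3 CPM of the others. Ttr, the transthyretin gene of the choroid plexus, ranged from 24.6 to 1260 CPM in the hippocampus and from 3.13 to 130 CPM in the cortex, and HSP70 replicate 5, the highest in the hippocampus, was at 13.7 CPM in the cortex.

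Immunoglobulin transcripts differed between animals in both tissues at once. Ighg1 ranged from 23.8 to 921 CPM in the hippocampus and from 76.2 to 944 CPM in the cortex, Igkc from 271 to 2730 and from 283 to 3160 CPM, and Jchain, the joining chain of secreted antibodies, from 13.5 to 91.8 and from 17.2 to 150 CPM. A hypothesis is that the animals differ in antibody-secreting cells or blood-borne transcripts in the brain, whatever the treatment. As deviations from the treatment means, log2 immunoglobulin CPM of hippocampus and cortex correlated over the 10 animals with r = 0.791 (permutation p = 0.00669, adjusted 0.0134, rho = 0.794) and with r = 0.651 without the 2 animals farthest from the median. The interferon score gave r = 0.720 (permutation p = 0.0191, adjusted 0.0191, rho = 0.782) and r = 0.565 without 2 animals, which is consistent with an interferon response that belongs to the animal in both tissues. What sets it in an animal was not tested.

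In the cortex with the Bc1 covariate, 273 of 14114 genes passed, of which 75 were higher and 198 lower with YB-1. Their median absolute log2 fold change was 0.62. All 273 had the same sign without the covariate and 154 of them an unadjusted p under 0.05 there. The libraries are the same, so this is no independent support. Of the 268 tested in the hippocampus, also with the Bc1 covariate, 164 had the same sign there. The tissues share animals, and without the covariate 56.7% of all genes tested in both had the same sign. The lists with at least 2 of the 273 were heat shock proteins (1 higher and 2 lower of 26), GABAergic markers (3 of 18, lower), nuclear noncoding RNAs (2 of 9, lower) and myelin genes (2 of 22, higher), with no test of enrichment. Without a library of the HSP70 group, in the order of replicates 1 to 5, the counts were 0, 46, 23, 99 and 501, and without one of the YB-1 group 199, 24, 159, 66 and 706.

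Averaged over both tissues with the animal as a random effect, limma called 0 of 14616 genes, with 636 at an unadjusted p under 0.05. The median, mean and test of a list differed in sign for some lists that did not pass, among them nuclear noncoding RNAs and olfactory bulb markers in the hippocampus and olfactory bulb and dentate markers in the cortex.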
